A study of Mus musculus with 6 samples.

How the data were processed

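The study measured messenger RNA in keratinocytes isolated from mouse skin. Per the labels, the floxed allele of Lama3 carries loxP sites around exons 50 to 53, on a C57BL/6 background. A tamoxifen-dependent Cre recombinase under the keratin 14 promoter removes these exons in basal keratinocytes when tamoxifen is given, here in chow at 400 mg per kg. The knockout mice carried 2 floxed alleles. The design text describes the controls as carrying 1 floxed and 1 wild type allele together with the same Cre, while the genotype label of the control samples reads wild type. Each group held 3 mice, named here control 1 to 3 and knockout 1 to 3 after the sample titles. Libraries were sequenced as paired 100-base reads, per the labels.

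The values used were whole-number counts per gene, deposited by the authors as 1 table with a column per library and Ensembl gene identifiers. Per the submitters' processing notes, TopHat 1.3.3, featureCounts 1.4.6 and Cuffdiff 1.3.0 were used with the mouse genome build GRCm38. The notes as used here give these names without their order or settings. The annotation release, the use of strand and the handling of reads that match several places were not given in the sources used here. Counts of near-identical gene copies (the Sprr2, Lce1, Stfa and Hba families, Krt6a and Krt6b) are therefore uncertain between copies, as are those of overlapping or antisense genes.

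The table held 45513 identifiers, of which 44585 (98.0%) were given a symbol through the GENCODE M21 annotation of GRCm38. The 928 identifiers without a symbol were kept in library sizes and tests. They held between 0.103% and 0.156% of each library's counts. Total counts lay between 20126395 and 28473479 per library. The precision of a low value is set by its count at these depths. The labels name separate mice, and each library was counted as 1 replicate. No 2 columns of a group were copies of one another.

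Differential expression was computed from the deposited counts with edgeR 4.0.16 under R 4.3.3. Libraries were scaled by TMM factors, genes were filtered with filterByExpr by group, and the dispersion and quasi-likelihood fits were robust. The design held the group only, and all 6 libraries entered. Of 25742 identifiers with any count, 15513 were tested. A gene was called higher or lower, and is said to have risen or fallen, at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. Every adjusted p of a single gene below comes from this test unless another is named. Fold changes are given as log2 of knockout over control with the standard error (SE). Levels are CPM, the count scaled by edgeR to library size and TMM factor, as mean ± SD over 3 libraries. Single values per library were compared with a 2-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

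The 41 gene lists were fixed before the data were examined, as were the design and the alternatives unless stated otherwise. They comprised 22 lists of skin biology, 17 lists of markers of other cell types or skin appendages, and 2 lists for RNA quality and sex. Of 775 list entries, 773 were found in the table. For the 38 lists with at least 4 tested members (the sex-linked list was used only to infer sex), camera in limma 3.58.1 was run with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over these lists. Camera with an estimated correlation and fry were run beside it. Counts of called members are given over all genes tested and adjusted over the list alone. Some genes stand on more than 1 list (S100a8, S100a9, Thy1, Pparg, Il1r2, Kit, Acta2 and Cxcl10 among them).

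Genes were named by a rule fixed before the data were examined, and a few items it covers are not reported here. It took the chains of laminin 332, the 6 highest and 6 lowest log2 fold changes, and the 6 smallest adjusted p. For the genes taken by fold or adjusted p it required an adjusted p under 0.05, a mean of at least 5 CPM, a symbol that is not a predicted-gene name, and all knockout libraries on one side of all controls. From each list it took the 2 called members with the smallest p or, where no member was called, the 1 member with the smallest p. The genes Krt1, Krt2, Krt5, Krt10, Krt14, Krt16, Lor, Tchh, Elovl6, Insig1, Igfbp3, Gadd45a, Cdkn1a, Mki67, Trdc, Trbc1, Kit, Ighm, Itgb4, Plec, Col17a1, Itga6, Col7a1, Ccl2, Il13 and Pmel fell outside it and were chosen after their values were seen.

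The alternatives were DESeq2 size factors and upper-quartile factors in edgeR, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom in place of edgeR, fits without robust estimation, the replicate number as a block, sex as a covariate, each library left out in turn, an adjusted p under 0.01, and a test against a fold of 1.5. After the data were seen, a fit with offsets for exon length and GC content was added, which covered 99.5% of the tested genes, as was a fit without the 191 cell type marker and mitochondrial genes. The procedure was tested on simulated counts with the means and library sizes of these 6 libraries. In them 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. Over 15335 genes, edgeR's quasi-likelihood test recovered 5.97% of the genes changed 1.5-fold, 50.7% of those changed 2-fold and 87.9% of those changed 4-fold. Of its 111 calls 13.5% were false. With a simulated trend of fold change with gene length, which these data also carry, 30.9% of 139 calls over 15322 genes were false, and 8.33% of 108 calls over 15246 genes with offsets for length and GC content. Far more genes (5612) were called in these data, so the simulated shares recovered and false do not carry over to them. Cuffdiff output was not used here.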

Results

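The data comprised RNA-seq gene counts from keratinocytes of 3 mice with a keratinocyte-specific loss of Lama3 and 3 control mice. Lama3 encodes the alpha chain of laminin 332, the laminin that anchors basal keratinocytes to the basement membrane through hemidesmosomes. Per the labels, tamoxifen-induced deletion was followed by a progressive loss of this laminin from the skin. Total counts were 23755818, 20126395 and 25429816 in controls 1, 2 and 3, and 24192158, 28473479 and 27768610 in knockouts 1, 2 and 3. The labels give no sex. Xist counts were 36549 in control 1, 21266 in knockout 1 and 26153 in knockout 2, against 9 to 43 in the other 3 libraries, which instead held 2293 to 3240 counts of the Y-linked gene Ddx3y. The controls thus came from 1 female and 2 males, and the knockouts from 2 females and 1 male.

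Lama3 itself was examined first. Lama3 (ENSMUSG00000024421) lies on chromosome 18 of GRCm38, from 12333819 to 12583013 on the plus strand, and fell to 91.8 ± 10.9 CPM in the knockouts from 132 ± 15.5 CPM in the controls (SD, n = 3 each). The log2 fold change was -0.53 (SE 0.14), with an adjusted p of 0.0215 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 3 control libraries held 141, 142 and 114 CPM and the 3 knockout libraries 97.3, 98.9 and 79.2 CPM, so every library lay on the side its label gives. The Lama3 call was lost without control 1, control 2 or knockout 1, with edgeR's adjusted p at 0.0620, 0.0584 and 0.0551. The numbering of the exons was assumed to follow the longest annotated transcript, which has 75 exons. Its exons 50 to 53 span 12528295 to 12531948 and hold 514 of its 10548 bases (4.87%). The annotation also holds a Lama3 transcript of 38 exons, for which this share was not computed. The gene counts also include the exons outside the deletion, so the whole-gene level is a partial check of the genotype.

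The other laminin genes did not move in one direction. Lamb3, the beta chain of laminin 332, was measured at 195 ± 52.9 CPM in the controls and 341 ± 96.4 CPM in the knockouts, a log2 fold change of 0.80 (SE 0.27) that was not called (edgeR's adjusted p = 0.0524). Lamb3 was called without knockout 3 (edgeR's adjusted p = 0.0185), with DESeq2 (adjusted p = 0.0106), with DESeq2 size factors in edgeR (0.0497) and without the marker and mitochondrial genes, a fit chosen after the data were seen (0.0495). The ratio of Lama3 to Lamb3 CPM was 0.701 ± 0.130 in the controls and 0.280 ± 0.0547 in the knockouts (n = 3 each, 2-sided exact permutation p = 0.1, the smallest possible). Among all 11 laminin chain genes 2 rose, 3 fell and 6 were not called (3 and 4 when adjusted over the list alone). Lama2, a chain of the laminins of muscle and nerve, fell by 2.61 on the log2 scale (SE 0.39). Without control 2 or without knockout 1 the number of chains that fell was 1. With offsets for exon length and GC content, chosen after the data were seen, 1 chain rose and 5 fell.

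**Figure D1:**
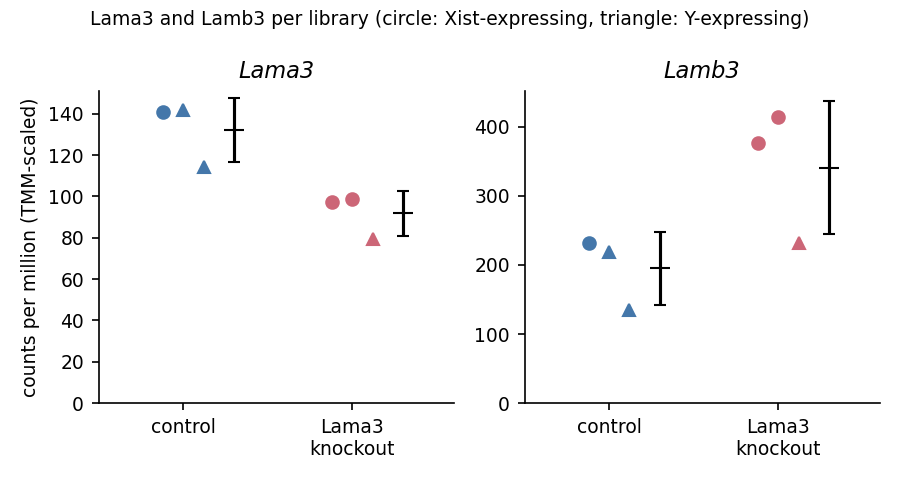
TMM-scaled CPM (vertical axes, from 0) of Lama3 and Lamb3 in each library, with mean and SD of 3 libraries as horizontal and vertical bars, and circles for libraries with Xist, triangles for libraries with Y-linked counts. Lama3 lay between 79.2 and 98.9 in the knockouts and between 114 and 142 in the controls, while the Lamb3 values of the groups overlapped.

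The comparison of all genes asked which transcripts differ in epidermal keratinocytes when Lama3 is lost. Of 15513 genes tested, 2693 rose and 2919 fell in the knockouts. A change of at least 2-fold was seen for 727 of those that rose and 1453 of those that fell. The first principal component, with 67.2% of the variance, separated the groups. In 51.7% of the tested genes the 3 knockout libraries lay wholly on one side of the 3 controls, against 10% by chance. The highest log2 fold changes were those of the small proline-rich protein gene Sprr2d (6.37, SE 0.99), the stress keratin gene Krt6b (6.04, SE 1.13), the calprotectin genes S100a9 (5.74, SE 0.96) and S100a8 (5.44, SE 1.15), the transmembrane protease gene Tmprss11g (5.68, SE 0.78) and the stefin gene Stfa2 (5.48, SE 0.94). The call of S100a8 was lost without control 3 (edgeR's adjusted p = 0.0699) and with no filter on low counts (0.0722), as was that of Krt6b with no filter (0.0578). The lowest folds belonged to the hair keratins and inner root sheath keratins Krt35 (-8.16, SE 0.78), Krt25 (-7.45, SE 0.66), Krt71 (-6.83, SE 0.68), Krt28 (-6.71, SE 0.68) and Krt27 (-6.12, SE 0.54), and to Ear2, an eosinophil-associated ribonuclease (-5.48, SE 0.65). The genes with the smallest adjusted p were Nccrp1 (3.23, SE 0.13, edgeR's adjusted p = 0.000148), Tgm1, Sprr4 (-2.26, SE 0.12), the steroid sulfate transporter Slc10a6 (3.87, SE 0.21), the membrane progestin receptor Paqr7 (-3.43, SE 0.19) and the heme synthesis enzyme Alad (-2.33, SE 0.14). The number of higher and lower genes was 1586 and 1714 without control 3, and 1681 and 1735 without knockout 1, and that of lower genes was 1750 without knockout 2. With upper-quartile factors in place of TMM, 30.6% of the called genes were higher, against 48.0% here.

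Genes of keratinocyte differentiation rose as a group. Of 29 suprabasal differentiation genes 20 rose, 2 fell and 7 were not called (21 and 2 adjusted over the list alone), with a median log2 fold change of 1.15 (camera adjusted p = 6.67e-13, adjusted p = 0.345 with an estimated correlation). Tgm1, the transglutaminase that cross-links the cornified envelope, rose from 32.1 ± 2.30 to 143 ± 10.1 CPM (log2 fold change 2.16, SE 0.11). Cnfn, cornifelin, rose by 2.30 (SE 0.17), and the spinous layer keratins Krt1 and Krt10 rose by 1.77 (SE 0.43) and 1.16 (SE 0.29). Lor, loricrin, rose by 3.33 (SE 0.60). The members that fell were Krt2 (-5.04, SE 1.35), a keratin of the upper epidermis, and Tchh (-1.47, SE 0.33), trichohyalin, which is also a protein of the hair inner root sheath. Without knockout 1 neither of these 2 was called. Of 16 late cornified envelope genes 5 rose and 11 were not called (0 adjusted over the list alone), with a median of 1.93 (camera adjusted p = 0.00368, adjusted p = 0.688 with an estimated correlation). Among them were Lce1f (2.43, SE 0.68) and Lce3c (1.88, SE 0.56). Knockout 3 had a mean log2 level of the late cornified envelope genes of 1.599, within the controls (0.956 to 2.22). Knockouts 1 and 2 lay above every control. The number of these genes that rose was 2 without control 1, control 2 or control 3, 0 without knockout 1, 1 without knockout 2 and 10 without knockout 3. It was 3 with upper-quartile factors or no filter on low counts, and 2 with a filter of 1 CPM, limma-voom or sex as a covariate. Leaving aside the stricter threshold and the test against a fold of 1.5, Lce1f lost its call in 9 alternatives and Lce3c in 5.

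Basal keratinocyte markers did not move as a set. Of 11 such genes 1 rose, 2 fell and 8 were not called (1 and 2 adjusted over the list alone), with a median log2 fold change of 0.04 and a camera adjusted p of 0.843. The basal keratin Krt5 was measured at 8174 ± 1364 CPM in the controls and 7349 ± 1297 CPM in the knockouts, and Krt14 at 4247 ± 511 and 4719 ± 614 CPM, and neither was called. Cdh3, P-cadherin, rose by 0.71 (SE 0.21), and Sostdc1, a secreted inhibitor of BMP and Wnt signals, fell by 1.57 (SE 0.17). The number of basal genes that rose was 3 without knockout 3, and the call of Cdh3 was lost without control 1, control 3, knockout 1 or knockout 2 (edgeR's adjusted p between 0.0688 and 0.0962). It was also lost with upper-quartile factors (0.0573) and with sex as a covariate (0.0590), and under both no basal gene rose.

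Genes that make the lipids of the skin barrier rose as well. Of 22 barrier lipid genes 17 rose, 2 fell and 3 were not called (17 and 2 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 3.27e-08, adjusted p = 0.345 with an estimated correlation). Alox12b, a lipoxygenase required for the barrier, rose from 14.3 ± 1.18 to 97.3 ± 32.9 CPM (log2 fold change 2.76, SE 0.26). Alox12e, another epidermal lipoxygenase, fell from 1670.9 ± 332.4 to 174 ± 31.3 CPM (-3.26, SE 0.24), and Elovl6, a fatty acid elongase, fell by 1.62 (SE 0.29). Sebaceous gland markers, some of which are lipid enzymes, also fell in the knockouts, with a median of -1.23. Of 20 cholesterol synthesis genes 10 rose, 2 fell and 8 were not called (10 and 3 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.0303, adjusted p = 0.699 with an estimated correlation). Srebf2, the transcription factor of this pathway, rose by 0.96 (SE 0.19) and the sterol carrier Stard4 by 0.96 (SE 0.17), while Insig1 (-0.75, SE 0.15) was among those that fell. The number of cholesterol genes that rose was 4 without control 3, 5 without knockout 1 and 6 without knockout 2, and the camera call was lost without control 3 (adjusted p = 0.0972), without knockout 1 (0.0794) and with sex as a covariate (0.0672). Knockout 3 had a mean log2 level of the cholesterol list of 6.40, within the controls (6.17 to 6.43), against 6.84 in knockout 1 and 6.65 in knockout 2.

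Genes of wounded or stressed epidermis showed the highest median of the 38 lists. Of 30 wound and stress keratinocyte genes 21 rose, none fell and 9 were not called (24 and 0 adjusted over the list alone), with a median log2 fold change of 3.08 (camera adjusted p = 2.06e-10, adjusted p = 0.440 with an estimated correlation). Krt6b rose from 28.9 ± 26.8 to 1895 ± 1520.5 CPM, and Krt16, its usual partner keratin, from 86.5 ± 36.5 to 2049 ± 1569.9 CPM (log2 fold change 4.57, SE 0.80). Knockout 2 lay below the other knockouts, with a mean log2 level of the list of 4.56 against 5.54 in knockout 1 and 6.23 in knockout 3, and with Krt6b at 356 CPM against 1934 and 3396 CPM. The EGF receptor ligand Tgfa rose by 1.84 (SE 0.17) and the interleukin 36 family member Il1f8 by 3.15 (SE 0.29). Of 14 antimicrobial genes 6 rose, 3 fell and 5 were not called (7 and 3 adjusted over the list alone), with a median of 2.16 (camera adjusted p = 0.00368, adjusted p = 0.512 with an estimated correlation). Lcn2, lipocalin 2, rose from 2.11 ± 0.853 to 28.2 ± 10.1 CPM (3.74, SE 0.37), and the protease inhibitor gene Slpi rose by 3.94 (SE 0.44).

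Neutrophil markers moved in the same libraries. Of 7 tested neutrophil markers 4 rose, 1 fell and 2 were not called (4 and 1 adjusted over the list alone), with a median of 0.62 and a mean of 2.23 (camera adjusted p = 0.0289, adjusted p = 0.438 with an estimated correlation). S100a8 and S100a9, which stressed keratinocytes also make, were among those that rose, as was Cxcr2, a chemokine receptor (4.55, SE 0.71). Cxcr2 reached 21.5 ± 11.4 CPM in the knockouts. Of these 7 markers 5 stand on another list too, and the camera call was lost without knockout 3 (adjusted p = 0.0662) and with no filter on low counts (0.0609).

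Cell cycle genes fell together. Of 36 cell cycle genes 30 fell, none rose and 6 were not called (32 fell adjusted over the list alone), with a median log2 fold change of -1.19 (camera adjusted p = 4.74e-11, adjusted p = 0.512 with an estimated correlation). Tyms, thymidylate synthase, fell from 34.2 ± 5.96 to 11.9 ± 1.79 CPM (-1.52, SE 0.17), and Nusap1, a spindle protein, from 23.8 ± 2.43 to 8.51 ± 2.36 CPM (-1.49, SE 0.21). The proliferation marker Mki67 fell by 1.31 (SE 0.34). Markers of hair shaft and sheath, whose cells arise from the dividing hair matrix, fell in the same libraries (median -4.47), as did T cell markers (median -1.36).

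Target genes of p53 rose, as did those of YAP. Of 18 p53 target genes 12 rose, none fell and 6 were not called (12 and 0 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 9.21e-05, adjusted p = 0.438 with an estimated correlation). Zmat3 rose by 1.21 (SE 0.19), Phlda3, an inhibitor of AKT signalling, by 1.08 (SE 0.14), and the cyclin-dependent kinase inhibitor gene Cdkn1a from 362 ± 23.8 to 605 ± 76.9 CPM. Of 22 YAP target genes, read out in many cells as a response to tension and adhesion, 12 rose, 2 fell and 8 were not called (15 and 2 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 0.000364, adjusted p = 0.472 with an estimated correlation). Amotl2 rose by 1.86 (SE 0.18) and Wwc1 by 1.12 (SE 0.12), both of which are also brakes on YAP. Igfbp3 (-3.72, SE 0.52) and Gadd45a (-0.91, SE 0.20) fell. Gadd45a is also a p53 target but was not on the p53 list, so the absence of falls there holds only for the listed genes.

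Interferon response genes fell. Of 36 such genes 17 fell, none rose and 19 were not called (18 fell adjusted over the list alone), with a median of -0.88 (camera adjusted p = 1.42e-06, adjusted p = 0.512 with an estimated correlation). Ifi27l2a fell from 80.8 ± 43.3 to 4.86 ± 1.65 CPM (log2 fold change -4.06, SE 0.46), and the T cell attracting chemokine Cxcl10 from 27.5 ± 3.54 to 7.29 ± 0.783 CPM (-1.92, SE 0.16). The number that fell was 11 without control 3. T cell markers fell in the same libraries. Of 20 of them 12 fell, 1 rose and 7 were not called (14 and 1 adjusted over the list alone), with a median of -1.36 (camera adjusted p = 5.77e-06, adjusted p = 0.512 with an estimated correlation). Cd3e, a chain of the T cell receptor complex, fell from 19.2 ± 3.48 to 6.23 ± 0.905 CPM (-1.63, SE 0.19), Cd3g fell by 1.99 (SE 0.28), and Trdc, the delta chain constant region expressed by the gamma-delta T cells of mouse epidermis, fell by 1.75 (SE 0.34). The member that rose was Trbc1 (1.04, SE 0.33), and no member was called higher without control 1, control 2, control 3, knockout 1 or knockout 3, with upper-quartile factors or with no filter on low counts.

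Other immune genes moved in both directions. Of 29 cytokine and chemokine genes 5 rose, 8 fell and 16 were not called (5 and 8 adjusted over the list alone, camera adjusted p = 0.330). Il1a rose by 2.30 (SE 0.29), and the monocyte chemokine Ccl2 fell by 2.02 (SE 0.34). Without knockout 1 the number that rose was 3, and without knockout 2 the number that fell was 5. Of 14 type 2 response, itch and alarmin genes 4 rose, 2 fell and 8 were not called (4 and 3 adjusted over the list alone, camera adjusted p = 0.629). Il31ra, a subunit of the interleukin 31 receptor, rose by 2.26 (SE 0.23) to 213 ± 47.9 CPM, and its partner Osmr rose by 0.93 (SE 0.12), while the cytokine Il13 fell by 3.02 (SE 0.44). Of these genes 2 rose without control 3, and 4 fell without knockout 1. None of 14 antigen presentation genes was called (0 adjusted over the list alone, camera adjusted p = 0.629), with H2-DMa at a log2 fold change of -0.92 (SE 0.33) and 6 called lower without control 2. Of 10 Langerhans cell markers 1 rose, 2 fell and 7 were not called (1 and 2 adjusted over the list alone, camera adjusted p = 0.643), with Cd207, langerin, at -1.68 (SE 0.49) and Il1r2 at -1.89 (SE 0.55). Neither of these 2 was called without control 1, control 3, knockout 1 or knockout 3. Of 14 monocyte and macrophage markers 4 rose, 1 fell and 9 were not called (4 and 1 adjusted over the list alone, camera adjusted p = 0.644), the complement genes C1qa (2.06, SE 0.36) and C1qb (1.66, SE 0.38) among them. Without any single library of controls 1, 2 and 3 and knockouts 1, 2 and 3, the number of these markers that rose was 2. The mast cell list had 3 tested members and the B and plasma cell list 2, too few for camera. Kit, which melanocytes also express, fell by 2.34 (SE 0.48), as did Ighm by 1.27 (SE 0.33).

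Markers of skin appendages and pigment cells fell in the knockouts. Of 27 hair shaft and sheath markers 19 fell, 2 rose and 6 were not called (19 and 2 adjusted over the list alone), with a median log2 fold change of -4.47 (camera adjusted p = 6.67e-13, adjusted p = 0.438 with an estimated correlation). Krt25 was at 31.5 ± 18.5 CPM in the controls and 0.172 ± 0.107 CPM in the knockouts, and Krt27 at 19.4 ± 11.4 and 0.272 ± 0.0579 CPM. No count of Krtap8-1 or Krt81 was found in the 3 knockout libraries, and with these 2 genes set to a bound from 3 counts over the group the median was again -4.47. The 2 members that rose were not called without knockout 1 or without knockout 2. Of 16 hair follicle stem cell markers, by contrast, 3 rose, 3 fell and 10 were not called (3 and 4 adjusted over the list alone, median 0.17, camera adjusted p = 0.747), with Ltbp2 up by 2.02 (SE 0.25) and Lrig1 at -0.86 (SE 0.16). Of 16 sebaceous gland markers 10 fell, 1 rose and 5 were not called (10 and 1 adjusted over the list alone), with a median of -1.23 (camera adjusted p = 7.16e-09, adjusted p = 0.345 with an estimated correlation). The wax synthase gene Awat2 fell from 39.1 ± 9.03 to 3.33 ± 1.46 CPM (-3.55, SE 0.35), and Soat1, which esterifies cholesterol, fell by 1.33 (SE 0.14). Of 11 melanocyte markers 7 fell and 4 were not called (7 adjusted over the list alone), with a median of -2.32 (camera adjusted p = 0.000798, adjusted p = 0.512 with an estimated correlation). Tyr, tyrosinase, fell by 3.93 (SE 0.53) and Dct from 69.2 ± 35.2 to 7.31 ± 3.29 CPM (-3.24, SE 0.49).

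Some markers of dermal and blood cells fell as well. Of 16 fibroblast markers 5 fell, 1 rose and 10 were not called (5 and 1 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 0.0321, adjusted p = 0.616 with an estimated correlation). Dcn, decorin, fell from 7.34 ± 1.25 to 2.42 ± 0.510 CPM (-1.60, SE 0.24), and Thy1, which T cells also express, fell by 1.21 (SE 0.17). The number of fibroblast markers that fell was 9 without control 1 and 3 without knockout 1, and the camera call was lost without control 2 (adjusted p = 0.0713), without control 3 (0.0690), and with upper-quartile factors (0.0677), a filter of 1 CPM (0.0525), limma-voom (0.0533) or sex as a covariate (0.108). Control 1 had a mean log2 level of the fibroblast list of 3.13, within the knockouts (2.97 to 3.19), against 3.85 in control 2 and 4.08 in control 3. Of 5 erythrocyte markers 4 fell and 1 was not called (4 adjusted over the list alone), with a median of -4.03 (camera adjusted p = 0.000500, adjusted p = 0.345 with an estimated correlation). Hbb-bs, a beta globin gene, fell from 7.82 ± 4.17 to 0.307 ± 0.300 CPM (-4.63, SE 0.67) and Hba-a1 by 2.41 (SE 0.35). Camera did not call the lists of 6 endothelial markers (2 fell and 4 were not called, adjusted p = 0.0901), 6 pericyte and smooth muscle markers (2 rose, 1 fell, adjusted p = 0.414), 4 adipocyte markers (1 fell, adjusted p = 0.117), 9 Schwann cell markers (2 fell, adjusted p = 0.330) or 7 skeletal muscle markers (0 called, adjusted p = 0.983). These counts were the same when adjusted over the list alone. Fry called the endothelial (adjusted p = 0.0376), adipocyte (0.0418) and Schwann cell (0.0384) lists lower. Plvap (-2.54, SE 0.42) and Egfl7 (-1.45, SE 0.37) fell in the endothelial list, Rgs5 (-1.57, SE 0.44) in the pericyte list, Pparg (-1.63, SE 0.17) in the adipocyte list, and S100b (-4.35, SE 0.67) in the Schwann cell list. Some of these folds rest on few counts in knockouts 1, 2 and 3, with 3, 0 and 3 for S100b, 3, 8 and 6 for Plvap, and 7, 4 and 7 for Rgs5. Atp2a1, a muscle calcium pump, was at 1.00 (SE 0.50) and not called. The call of Egfl7 was lost without control 2, control 3, knockout 1, knockout 2 or knockout 3 (edgeR's adjusted p between 0.0512 and 0.0705), and that of Rgs5 without the same libraries (0.0558 to 0.103), with DESeq2 (0.0636) and with sex as a covariate (0.0551). Without knockout 3 the number that fell was 3 adipocyte and 4 Schwann cell markers.

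Some adhesion and matrix genes changed, while camera with the group as the only term, all 6 libraries and the filter on low counts called none of the 3 lists of adhesion, other basement membrane and matrix protease genes. Of 15 hemidesmosome and adhesion genes 4 rose, 1 fell and 10 were not called (4 and 1 adjusted over the list alone, median 0.38, camera adjusted p = 0.0901). The integrin gene Itgb6 rose from 9.71 ± 1.37 to 20.2 ± 2.44 CPM (log2 fold change 1.06, SE 0.16). The hemidesmosome genes Itgb4 (0.90, SE 0.22), Plec (0.71, SE 0.16) and Dst (0.91, SE 0.17) rose, while Col17a1 (0.65, SE 0.29) and Itga6 (0.24, SE 0.33) were not called. Camera called this list without control 1 (adjusted p = 0.0457) or knockout 3 (0.0102) and with no filter on low counts (0.0154). Without knockout 3, 8 of these genes rose, and with offsets for exon length and GC content, chosen after the data were seen, 1 rose and the call of Dst was lost (edgeR's adjusted p = 0.0878). Of 16 other basement membrane genes 3 rose, 3 fell and 10 were not called (3 and 3 adjusted over the list alone, camera adjusted p = 0.819). The anchoring fibril collagen gene Col7a1 rose from 194 ± 20.1 to 344 ± 34.9 CPM (0.82, SE 0.14) and Col4a4, a type IV collagen chain, by 1.86 (SE 0.29), and Npnt, nephronectin, fell from 49.1 ± 13.3 to 8.20 ± 0.819 CPM (-2.58, SE 0.21). Of 21 matrix proteases and inhibitors 4 rose, 2 fell and 15 were not called (3 and 2 adjusted over the list alone, camera adjusted p = 0.285, and 0.0167 with no filter on low counts), with the collagenase gene Mmp13 up by 4.97 (SE 0.59) from 0.306 ± 0.354 to 9.36 ± 1.85 CPM and the gelatinase gene Mmp2 by 1.45 (SE 0.18). Of 22 TGF-beta response and fibrosis genes 5 rose, 1 fell and 16 were not called (5 and 1 adjusted over the list alone, camera adjusted p = 0.0602, fry adjusted p = 0.0240). Camera called this list in 6 of the alternatives, with adjusted p between 0.0167 and 0.0465 (without control 3, knockout 1 or knockout 3, with upper-quartile factors, with no filter on low counts and with a filter of 1 CPM). Acta2, smooth muscle actin, rose from 1.62 ± 0.408 to 18.2 ± 4.95 CPM (3.49, SE 0.29) and Pmepa1, a feedback inhibitor of TGF-beta signalling, by 2.34 (SE 0.20).

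General stress lists held changes of single genes. Of 23 NRF2 and xenobiotic response genes 6 rose, 5 fell and 12 were not called (6 and 6 adjusted over the list alone, camera adjusted p = 0.629). The cystine transporter gene Slc7a11 rose from 1.06 ± 0.398 to 23.4 ± 14.5 CPM (log2 fold change 4.45, SE 0.65) and Hmox1, heme oxygenase, by 1.09 (SE 0.19). Of 18 unfolded protein response genes 4 rose, 3 fell and 11 were not called (4 and 3 adjusted over the list alone, camera adjusted p = 0.905), with Chac1 up by 1.24 (SE 0.28) and Sesn2, also a p53 target, by 0.65 (SE 0.13). Of 21 immediate early and heat shock genes, which tissue handling can induce, 2 rose, 1 fell and 18 were not called (2 and 1 adjusted over the list alone, camera adjusted p = 0.689), with Hspa1b up by 0.72 (SE 0.18) and Egr3 by 0.58 (SE 0.15). The number of NRF2 genes that fell was 2 without control 2 or knockout 2 and 3 without control 1 or knockout 3. Without control 3, knockout 1 or knockout 2 none of the unfolded protein response genes that fell was called, nor without knockout 1 any of the immediate early and heat shock genes that rose. The call of Hspa1b was also lost without control 1 (edgeR's adjusted p = 0.0574) and that of Egr3 without control 3 (0.0506). The number of immediate early and heat shock genes that rose was 4 with sex as a covariate and 5 with offsets for exon length and GC content. With these offsets 2 NRF2 genes and 1 unfolded protein response gene fell.

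Mitochondrial transcripts fell. Of 15 mitochondrially encoded genes 11 fell and 4 were not called (14 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 0.000153, adjusted p = 0.554 with an estimated correlation). Their share of all counts was 7.36% ± 2.55 in the controls and 3.38% ± 0.899 in the knockouts (n = 3 each, 2-sided exact permutation p = 0.1, the smallest possible). The share of cytosolic ribosomal protein genes was 6.90% ± 1.37 and 4.25% ± 0.560 (exact permutation p = 0.1). The number of mitochondrial genes that fell was 2 without control 2, 1 without control 3, 1 without knockout 1 and 2 without knockout 2. It was 6 with sex as a covariate and 6 without robust estimation. With offsets for exon length and GC content, chosen after the data were seen, it was 0, and the camera adjusted p was 0.185.

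Over the 38 lists camera with the preset correlation called 9 higher and 9 lower. With an estimated correlation none was called, the lowest adjusted p being 0.345, and fry, which asks whether the genes of a list move on balance in one direction, called 7 higher and 8 lower. The median, the mean and the camera direction differed in sign for the laminin chain, basal keratinocyte, type 2 and itch, unfolded protein response, immediate early and heat shock, monocyte and macrophage, pericyte and skeletal muscle lists, and camera called none of these.

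**Figure D2:**
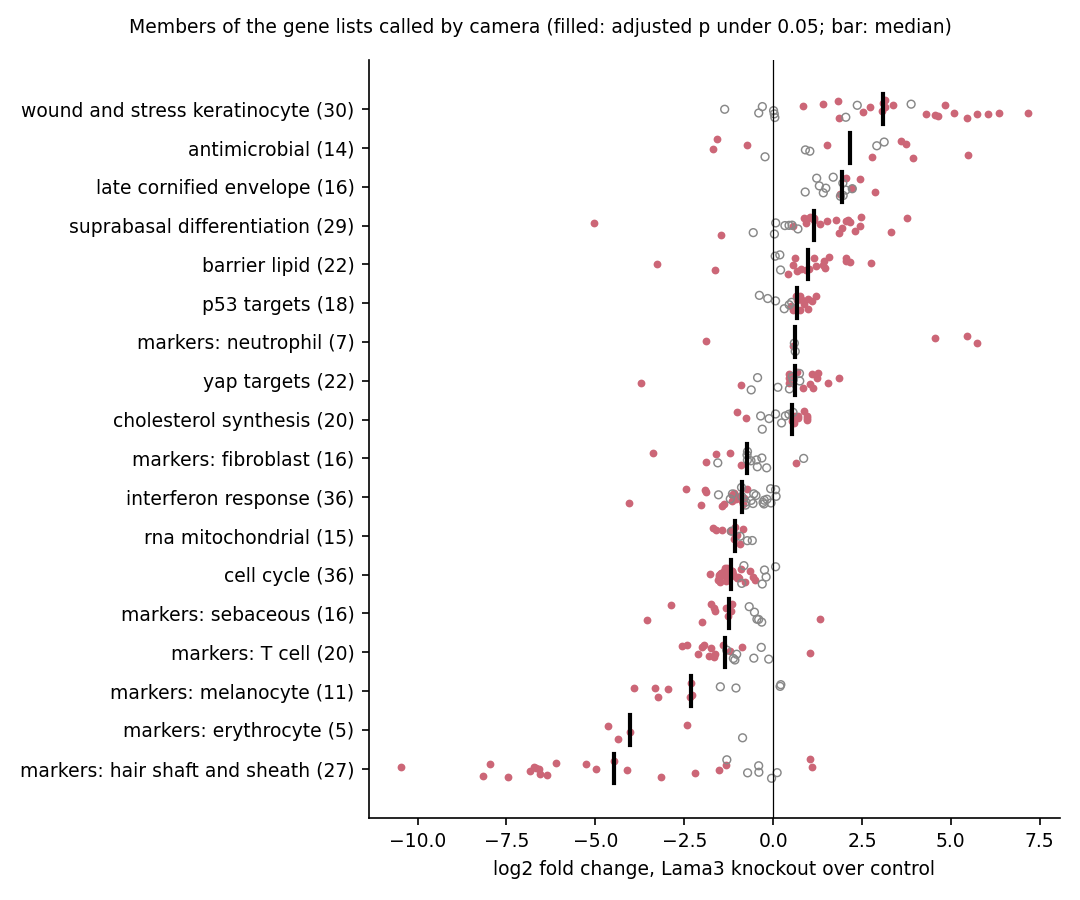
Log2 fold change of knockout over control (horizontal axis) for each tested member of the lists called by camera with the preset correlation, the number of members in parentheses, filled points for genes called by edgeR's quasi-likelihood test and black bars for medians. The wound and stress list had the highest median (3.08) and the hair shaft and sheath list the lowest (-4.47), and Krtap8-1 and Krt81 of the latter, without counts in the knockouts, are drawn at fitted values that are no bound.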

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

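The fits with offsets for exon length and GC content and without the marker genes were chosen after seeing the data. Every gene called in the main comparison and still tested kept its sign in each alternative, except that 99.7% did so with the offsets. Fewer kept their call and direction: 56.7% without control 3, 58.0% without knockout 1, 60.5% without knockout 2, 64.7% without control 1 and 75.0% with the offsets. In the other fits this share lay between 80.4% and 99.3%. Counts of higher and lower genes stayed within 1.5 times of 2693 and 2919 with DESeq2 size factors (2774 and 2867), no filter on low counts (2859 and 2858), a filter of 1 CPM (2581 and 2767), DESeq2 (3089 and 3163), limma-voom (2636 and 2909), fits without robust estimation (2692 and 2912), sex as a covariate (2378 and 2696), the offsets (2805 and 2168) and without the marker and mitochondrial genes (2660 and 2889). With upper-quartile factors 1756 rose and 3988 fell, as this scaling moved the median of all genes by -0.15 on the log2 scale and calls are relative to it. The stricter threshold of 0.01 left 1115 and 1009, and the test against a fold of 1.5 left 527 and 692, which follows from their construction. Leaving out 1 library at a time gave 1586 to 2754 higher and 1714 to 2771 lower genes, with fewer samples in each fit. Lama3 ranged from -0.62 to -0.42 over these fits and from -0.75 to -0.49 over the other alternatives, and its call was lost without control 1 (-0.48), control 2 (-0.46) or knockout 1 (-0.56), with edgeR's adjusted p between 0.0551 and 0.0620. Of the 18 gene lists called by camera with the preset correlation of 0.01, 0 were called with an estimated correlation. The estimates for these lists ran from 0.00718 (erythrocyte) to 0.862 (mitochondrial), with 0.607 for cell cycle and 0.636 for T cells. The preset p values thus assume less correlation than most of these lists show. This alone does not account for the lost call of the erythrocyte list, whose estimate lay below the preset 0.01. Its camera p was 0.000158 with the preset correlation and 0.0191 with the estimated one (adjusted p 0.000500 and 0.345). Whether the correlation accounts for the other lost calls was not tested. Fry called 15 lists, 11 of these 18 and 4 others (TGF-beta response, endothelial, adipocyte and Schwann cell). Of the other 84 named genes, 69 kept their side of the threshold in every alternative fit in which they were tested. In at least 1 such fit 13 lost their call, and Lamb3 and H2-DMa gained one. The stricter threshold and the test against a fold of 1.5 were not applied to these genes singly. With camera at the preset correlation, over the alternatives in scaling, filter, model and libraries, 29 of 38 lists kept their side, 4 lost their call somewhere (cholesterol synthesis, neutrophil, fibroblast and mitochondrial) and 5 gained one (hemidesmosome and adhesion, matrix proteases, TGF-beta response, endothelial and adipocyte), and the cause was not tested. The replicate block gave 2422 higher and 2701 lower genes. The same-number correlations between controls and knockouts were -0.20, -0.07 and 0.38, so the numbers were not read as pairs, and not every library correlated best with its own number. Under the block S100a8, Lce1f and Cd207 lost their call and Lamb3 and the hemidesmosome and adhesion list gained one. Depth limits genes of a few counts per library, such as Krt35 in the knockouts or most Lce1 genes.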

Other observations

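The gene families of this paragraph, the glucocorticoid targets, and the tests on basal keratinocyte loss, on a common dilution and on whole hair follicles were chosen only after the results were seen. Many genes of protein synthesis and respiration fell in the knockouts, though these families were not tested as sets. Of 80 tested cytosolic ribosomal protein genes 42 fell, none rose and 38 were not called (median log2 fold change -0.62), and of 72 nuclear genes of the respiratory chain 59 fell, none rose and 13 were not called (median -0.72), against 18.8% lower among all genes tested. With upper-quartile factors these medians were -0.77 and -0.87. With offsets for length and GC content they were -0.40 and -0.42, with 23 and 33 genes lower and 1 and 0 higher, against 14.0% lower among all genes. Of 11 tested Skint genes, a keratinocyte family of which Skint1 is needed for the gamma-delta T cells of mouse epidermis, 7 fell and none rose (median -0.66, -0.81 with upper-quartile factors and -0.28 with the offsets, where 4 fell and 2 rose). Of 81 tested identifiers without a symbol, or with a symbol shared by several identifiers, 7 rose by more than 16-fold. Among them was ENSMUSG00000081977, from 14.0 ± 9.14 to 267 ± 69.1 CPM.

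The called genes were compared with those of other groupings. The real split of the 6 libraries gave 5612 called genes by edgeR's quasi-likelihood test, and of the 10 splits into 3 and 3 only this 1 gave as many. The highest of the others, the split by sex, gave 5, and 10 splits are too few for a share under 0.05. Every other split placed knockouts and controls in both groups, which widens the spread within groups, so few calls were likely in advance. The 5 calls of the split by sex thus do not measure how many genes differ by sex. With sex as a covariate 84.4% of the called genes kept their call and direction, which argues against the unequal mix of sexes as the whole cause. A test of the interaction of sex with genotype called 0 genes with edgeR (1034 at an unadjusted p under 0.05), on 2 residual degrees of freedom.

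The fall of the cell cycle genes was weighed against 3 explanations. With offsets for length and GC content 28 of 36 were still called lower, which argues against a trend with gene length as its cause. The basal keratinocyte list had a median of 0.0424 (95% interval over resampled members -0.30 to 0.51) against -1.19 for the cell cycle list, which argues against a loss of basal keratinocytes as a whole. This interval treats genes as independent and does not measure the spread between mice. By library, the mean log2 level of the basal list was 8.07 to 8.31 in the controls and 7.92 to 8.27 in the knockouts. A loss of dividing hair matrix cells may contribute and cannot be told apart from slower division between follicles, since 3 controls are too few. The control with the least hair shaft RNA, control 1, had a mean cell cycle level that differed by -0.157 (log2) from that with the most, control 2, but control 3, with a hair shaft level between theirs, had the highest cell cycle level (4.88 against 4.48 and 4.64).

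Markers of hair shaft, melanocytes, sebaceous glands and T cells fell together. With the length and GC offsets 46 of the 48 members called lower (95.8%) were still called lower, which argues against a length trend. The monocyte and macrophage list had a median of -0.00647 (-0.50 to 0.94) against -1.36 (-1.78 to -1.05) for the T cell list. This argues only against an equal dilution of all minor cells as the sole change. Medians were also negative for the fibroblast (-0.72), endothelial (-0.90), adipocyte (-0.73), Schwann cell (-1.15) and erythrocyte (-4.03) lists. Those of the pericyte (-0.17) and skeletal muscle (-0.08) lists were small, and that of the neutrophil list was positive (0.62). A dilution offset in some lists by a rise of their cells was not tested and stays open. The hair follicle stem cell list had a median of 0.173 (-0.40 to 0.40) against -4.47 (-6.57 to -1.32) for hair shaft and sheath, which argues against a loss of whole follicles, although some stem cell markers are also made by other keratinocytes. The intervals of this paragraph treat genes as independent and do not measure the spread between mice. Both comparisons of medians were chosen after the results were seen. A difference in hair cycle stage between the groups, a different yield of these cells during isolation, and a loss of growing follicles with the genotype all stay open and were not tested, as the labels give neither age nor hair stage.

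Short genes were lower and long genes higher in the knockouts. The median log2 fold change ran from -0.45 in the shortest of 10 equal classes of exon length to 0.22 in the longest, and Spearman's rho across genes, which are not independent replicates, was 0.256. Without ribosomal protein and mitochondrial genes rho was 0.242, which argues against these families alone. The mean length slopes of the groups differed by 1.29 times the largest range within a group, so a length bias of RNA quality or library preparation cannot be told apart from an effect of the genotype, as the difference follows the groups.

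A raised glucocorticoid response is a hypothesis for part of the changes. It was prompted by the rise of Fkbp5, a classic target gene (log2 fold change 2.29, SE 0.23), which was set aside for the test. Of 12 other known target genes, 2 (Zbtb16 and Cdkn1c) rose and none fell, against 2693 that rose among all 15513 genes tested. The 12 targets had a median of 0.45. Camera gave p = 0.0323 with the preset correlation and p = 0.413 with an estimated one, neither adjusted for the other lists. The first value allows a small common rise, for a list chosen after the results were seen, and the second leaves such a rise unsupported.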
